A study of Drosophila melanogaster with 2 samples.

How the data were processed

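Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was carried out on whole adult female Drosophila melanogaster carrying a transgene for Ovo with GFP at its C terminus. Ovo is a zinc-finger transcription factor of the female germline. Per the labels, chromatin was sheared by sonication to 200 to 800 bp, precipitated with an antibody against GFP and collected as biological replicates numbered 1 and 4. The 2 replicates form 1 group, so no comparison between conditions was possible, and the comparisons were between replicates, between classes of genomic region and between peaks and matched background positions. The labels name a control experiment; its reads and those of the immunoprecipitated libraries were not analysed here.

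The authors deposited 8 peak lists, 4 on the genome build dm6 and 4 on dm3. For each build there is a relaxed list for each replicate, a relaxed list called on the reads of both replicates together (the pooled list), and a thresholded list. Per the text record deposited with the samples, the relaxed lists were called against a control alignment and hold peaks and background. The thresholded list was made from them with the irreproducible discovery rate (IDR) procedure, which compares the ranks of peaks between replicates to set how many are kept. The peak caller and the IDR limit are not given in the sources used here. Each peak carries a score, the authors' enrichment value against the control, which was used only to rank and describe peaks within a list. Each peak also has a q-value, deposited as -log10 of q, which stood at the highest value of the list for 59.6% of the thresholded dm6 peaks and was therefore not used for ranking. The third deposited value is the summit position. Most peaks had a fixed width: 440 bp was the width of 94.2% of the thresholded dm6 peaks, and the summit lay at the middle in 94.5%. The thresholded lists were identical to the 4477 (dm6) and 2986 (dm3) peaks of highest score in the pooled lists. The files hold no read counts, so the sequencing depth of each replicate is unknown and intervals cover the counting of peaks or genes only.

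Coordinates were used on dm6 alone. The reference was Release 6 of the Drosophila genome with the Ensembl release 115 annotation, restricted to the 6 chromosome arms X, 2L, 2R, 3L, 3R and 4, on which all dm6 peaks lie. No coordinates were converted between builds. Positions are 1-based. Transcription start sites (TSSs) were those of all annotated transcripts of 13945 protein-coding genes, 19607 in number.

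Replicates were compared by the share of the 4477 peaks of highest score in replicate 1 with a summit within 100 bp of one of the 4477 of highest score in replicate 4, against 1000 circular rotations of the summits along each arm, which keep their spacing. The smallest p that 1000 rotations can give is 0.000999. The rank agreement was a Spearman correlation across thresholded peaks with a 95% interval from 500 bootstrap draws of peaks; peaks are not independent replicates. Peaks per Mb had exact Poisson intervals, and the ratio of X to the large autosomal arms (2L, 2R, 3L, 3R) was tested with a conditional exact binomial test. The share of summits within 500 bp of a TSS was compared with 1000 rotations (one-sided), and each summit was given 1 class in the order promoter (within 500 bp of a TSS), 5' UTR, 3' UTR, coding exon, intron and intergenic, with 100 rotations. These classes use protein-coding genes alone, so an intergenic summit may lie in a non-coding gene. Intervals of shares are 95% Clopper-Pearson intervals.

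A gene counted as having a peak where a thresholded summit lay within 500 bp of any of its TSSs. Members of 16 gene lists were compared with all other protein-coding genes by a two-sided Fisher's exact test with Benjamini-Hochberg adjustment over the 16 lists. The lists cover germline and maternal functions, follicle cells, marker genes of other adult tissues and general cell functions. They were written before the data were examined, as were the tests and the alternatives unless stated otherwise. The symbol of nanos was brought up to date in 3 lists after a first look at the counts, and 15 outdated symbols were matched through their synonyms. 7 symbols stayed unmatched. The lists hold 467 different genes, some of them in more than 1 list. Peaks at divergent or overlapping promoters counted for every gene they touched: 1775 of the 3283 genes with a peak (54.1%) shared their peak with another gene, so genes are not fully independent in these tests.

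The Ovo core site TAACNGT was searched on both strands within 50 bp of each summit and in windows of equal size 500 bp to either side, with a two-sided exact McNemar test against each side. A permuted pattern, TNACAGT, and the sites of other factors served as controls; with A at N the permuted pattern equals a form of the Ovo site. All 2080 distinct 6-mers were tested at summits against the flanking windows with Fisher's exact test and Benjamini-Hochberg adjustment. Core promoter elements were compared between genes with and without a peak: the Initiator (TCAKTY) within 10 bp of the TSS, the TATA box (TATAWA) from -40 to -20, and the DRE (TATCGATA) and Motif 1 (GGTCACAC) from -100 to 50, at 1 TSS per gene, the one nearest to a summit or otherwise the 5'-most.

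The genes named were chosen by a rule: ovo and otu, the nearest protein-coding gene of the 10 thresholded peaks of highest score, and for each list up to 4 members with the highest-scoring peak at a TSS and the alphabetically first member without one. A gene that this rule names is not reported here. Alternatives were a stricter list of the 1000 peaks of highest score, the 4477 best peaks of each replicate alone, TSS windows of 100 and 1000 bp, other overlap rules, site patterns and windows, the dm3 lists, and rotation in place of Fisher's test. Alternatives added after seeing the data were the 15000 peaks of lowest score in the pooled list as the reference, a ratio per Ovo site, a gene background without ribosomal protein genes, gene families defined by symbol, and the Ovo site split by its variable base.

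The scripts were tested on simulated data. With rotated summits and no planted effect, the site ratio of summits to flanks was 1.04 for 4477 peaks, 0 of 2080 6-mers and 0 of 4 promoter elements were called, and 0 of 100 random gene lists had p under 0.05. Rotated summits were near a TSS in 11.5% of cases and real summits in 63.7%, so differences between promoters and their flanks were not simulated. A site planted in 10% of windows put its 2 6-mers first, and 59.5% of summits were matched between lists simulated with 60% shared. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.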

Results

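Binding sites of GFP-tagged Ovo were mapped by ChIP-seq in whole adult females, with 2 biological replicates (numbered 1 and 4) of 1 group. The question was where on the genome the tagged protein sits. On dm6, each replicate contributed a relaxed list of 30000 peaks, the pooled list also held 30000, and the thresholded list held 4477 peaks with authors' scores from 74.9 to 1349 and a median of 116. Read depth is unknown, and because the thresholded list merges the replicates, its values have no standard deviation between replicates. A precipitation from flies without the tag was not analysed here, so no peak could be set against one.

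Ovo-GFP peaks were found mainly at promoters, and the genes at which they were found included ovo itself, many regulators of the female germline and oocyte, and most ribosomal protein genes. Of 13945 protein-coding genes, 3283 (23.5%) had a thresholded summit within 500 bp of a TSS. After rotation of the summits the mean was 3.74%.

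At ovo (X, 5048273 to 5070929, plus strand), 8 thresholded summits lay within the gene or 5 kb either side, 5 of them inside the gene. Of its 2 promoter peaks, the stronger (X, 5064032 to 5064269) had a score of 385 and rank 132, with rank 118 in replicate 1 and 145 in replicate 4. Its summit at 5064142 lay at -91 bp from the TSS at 5064233, and an Ovo core site, TAACNGT, stood at 5064148 to 5064154. The other promoter peak (X, 5047967 to 5048406, summit 5048187, score 163.6, rank 1204), at the first ovo TSS at 5048273, had no core site within 50 bp of its summit. The peak with the highest score in the region (X, 5046847 to 5047163, score 441, rank 86) lay outside protein-coding genes, upstream of the first ovo TSS and within the non-coding RNA gene lncRNA:CR44833 (X, 4956646 to 5063868, minus strand), and likewise had no core site at the summit. At otu (X, 8485008 to 8489535, minus strand), an oogenesis gene long known as a target of Ovo, the peak at X, 8489236 to 8489675 had a score of 122 and rank 2079. Its summit lay 79 bp inside the gene with a core site within 50 bp.

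**Figure D1:**
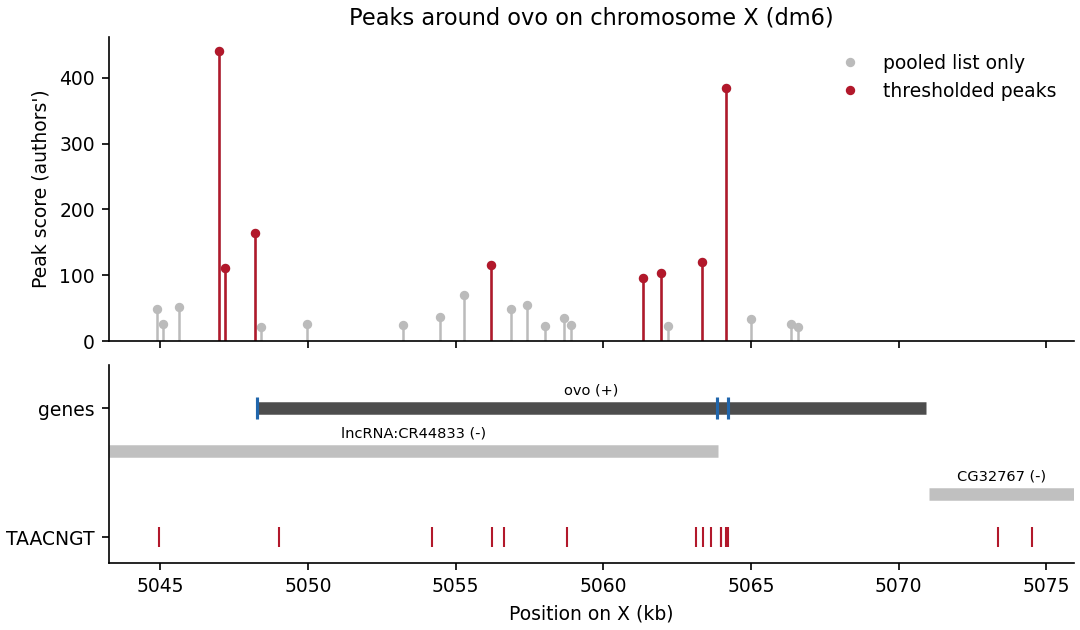
Peaks around ovo on chromosome X (dm6). The upper panel gives each summit's position (kb) and the authors' score in the pooled list, with thresholded peaks in red and the others in grey; the lower panel shows gene extents, ovo TSSs (blue ticks) and TAACNGT sites (red ticks). The thresholded peaks with the highest scores, 441 and 385, lie upstream of the first ovo TSS and at its internal promoter.

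The 10 peaks with the highest score lay nearest to CG14100, CG11050, Or45b, subdued, Tlk, Miga, Ubr3, Gapdh2, mRpL41 and Lsd-2. Gapdh2 encodes a glycolytic enzyme, Lsd-2 a lipid droplet protein, mRpL41 a mitochondrial ribosomal protein and Ubr3 a ubiquitin ligase. The first peak (3L, 19590445 to 19590812, score 1349) was at -93 bp from the TSS of CG14100 and ranked 1 in both replicates. The peak at 2L, 6612415 to 6612894 (score 1119) was intronic, 1021 bp from the CG11050 TSS, and that nearest to Or45b (2R, 9553972 to 9554318, score 1111) lay outside protein-coding genes, at -5447 bp. The promoters of subdued (3R, 19641131 to 19641446), Miga (X, 8437583 to 8437943), Gapdh2 (X, 15867831 to 15868144) and mRpL41 (2R, 15217599 to 15217899) carried the other promoter peaks, with scores of 1017, 905, 864 and 820. Introns held the peaks nearest to Tlk (X, 3741906 to 3742380), Ubr3 (X, 7938337 to 7938681) and Lsd-2 (X, 15075501 to 15075812), with scores of 915, 872 and 813. Of these 10 peaks, each ranked among the first 10 of replicate 1, and in replicate 4 the lowest was the Lsd-2 peak at rank 16. The core site stood within 50 bp of the summits nearest to Or45b, subdued, Miga, Ubr3 and Gapdh2.

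Genes of 3 germline and maternal lists had peaks more often than other genes. Gene activity was not measured here, and the other genes include any protein-coding gene. A preference for germline genes could thus not be told apart from signal at active promoters. Of 20 germline identity genes, 13 had a peak at a TSS (65.0%, 95% interval 40.8 to 84.6), against 23.5% of the other genes (odds ratio 6.05, Fisher's exact test, adjusted p = 0.0005). Without replicate 1 the count was 15 of 20 and the odds ratio 9.86. They included hts, which encodes an adducin of the fusome (2R, peak 19424924 to 19425363, score 300.3), zpg, a germline gap junction protein (3L, 6605867 to 6606306, score 224), and piwi, which acts in transposon silencing (2L, 10987001 to 10987440, score 154). AGO3 was the first member without one. Among 24 germ plasm and axis genes, 13 had a peak (54.2%, interval 32.8 to 74.4, odds ratio 3.85, Fisher's exact test, adjusted p = 0.00458): the chaperone gene Hsp83 (score 362), BicC (285), CycB (189) and osk, the organiser of germ plasm (174), led the list, and the peaks of CycB (2R, 22806192 to 22806631) and osk (3R, 8934933 to 8935051) had a core site at the summit. The bru1 gene had none, but in the best peaks of replicate 4 alone a summit lay 248 bp from its TSS. Of 29 genes of meiosis and egg activation, 14 had a peak (48.3%, interval 29.4 to 67.5, odds ratio 3.04, Fisher's exact test, adjusted p = 0.00806), led by smg, a repressor of maternal mRNAs (score 350), c(2)M of the synaptonemal complex (208), the poly(A) polymerase gene wisp (186) and plu (163); Cks30A had none. These 3 lists share members, 10 of the germline identity genes also standing in another list. The core site stood within 50 bp of the summit in 2 of 13 germline identity promoter peaks, those of ovo and otu. The counts were 4 of 13 for germ plasm and axis and 4 of 14 for meiosis and egg activation. Over all promoter summits the share was 13.7%, and the lists were not tested against it.

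Genes of mRNA decay and translation control, a general function with many maternal members, had a peak in 15 of 30 cases (50%, interval 31.3 to 68.7, odds ratio 3.26, Fisher's exact test, adjusted p = 0.00558). The strongest were at eIF4EHP (3R, 24109009 to 24109361, score 621), smg, tral (score 309) and AGO1 (score 287); 4E-T had no peak at its TSS. Ribosomal protein genes stood highest of the 16 lists, with a peak at 66 of 85 (77.6%, interval 67.3 to 86.0, odds ratio 11.5, Fisher's exact test, adjusted p = 1.04e-24). RpS27 (3R, 25247395 to 25247658, score 644), RpL7 (2L, 10200920 to 10201154, score 531) and RpS28b (score 438) had the strongest peaks, and RpL10 was the first without one. Only 2 of the 66 ribosomal protein promoter peaks (3.03%) had the core site within 50 bp of the summit, against 14% of 2785 other promoter peaks (Fisher's exact test, p = 0.00605), and the flanking windows of the ribosomal protein peaks held it in 2.27%.

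Piwi-interacting RNA genes had a peak in 11 of 34 cases (32.4%, Fisher's exact test, adjusted p = 0.363) and DNA replication genes in 12 of 39 (30.8%, adjusted p = 0.457), which did not pass the test. The piRNA genes with the strongest peaks were papi (score 452), squ (188), spn-E (174) and piwi, and the replication genes were dup (259.97), E2f1 (193), RnrS (177) and Mcm2 (142); AGO3 and Cdc45 had none.

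The follicle cell, eggshell, cuticle and other tissue lists did not pass the test for more peaks at the TSS than other genes. The eggshell list was not split by the cells that express its genes. Follicle cell regulators had a peak at 6 of 25 (24.0%, Fisher's exact test, adjusted p = 1), with aop (score 100.99), Egfr (88.9), N (83.2) and kek1 (82.9) leading and EcR without one at a TSS in the thresholded list. In the best peaks of replicate 4 alone Egfr and kek1 had no summit within 500 bp of a TSS, whereas EcR had one at 296 bp, and at 190 bp in those of replicate 1 alone. With summits counted anywhere in the gene body or 500 bp upstream, 13 of the 25 had one (odds ratio 3.05, Fisher's exact test, adjusted p = 0.0116). Eggshell genes had 3 of 27 (11.1%, Fisher's exact test, adjusted p = 0.306), which were fs(1)M3 (score 250.8), fs(1)N (170.2) and clos (92.8, not within 500 bp in replicate 4 alone), whereas the chorion gene Cp15 had none. The shares were 4 of 25 for muscle genes, among them Tm1 (score 139), Actn, Mef2 and Zasp52 but not Act57B, and 4 of 22 for photoreceptor genes, among them rdgB (162), Galphaq, rdgC and Gbeta76C but not Arr1. Neuronal genes had 3 of 23, elav (score 356), nrv3 and Syx1A (not within 500 bp in replicate 1 alone), with Appl the first without one. Yolk and fat body genes had 2 of 14, Adh (179) and bmm (154), with DptA the first without one. None of these 4 lists passed the test (adjusted p from 0.457 to 0.855). Fewer peaks than at other genes were found at digestive enzyme genes of the gut, such as Amy-d, with 0 of 39 (interval up to 9.03%, Fisher's exact test, adjusted p = 0.000304), and at testis-specific genes, with 1 of 33 (bol, score 96.7, but not Mst77F; odds ratio 0.101, adjusted p = 0.00806). Cuticle genes known as targets of Shavenbaby, the somatic protein made from the same locus as Ovo, had 0 of 14 (interval up to 23.2%, Fisher's exact test, adjusted p = 0.103). The first of them in the alphabet was cyr. With summits counted in the gene body or 500 bp upstream they had 3 of 14 (21.4%, odds ratio 0.766). Chromatin came from whole females, so the tissue in which a peak arose is not known. Whether the tag also marks Shavenbaby was not tested.

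Of the genes with a peak, 54.1% shared it with another gene, which the tests on lists treat as separate. In total 5 lists had peaks more often and 2 less often than other genes. With the 1000 peaks of highest score only, the ribosomal protein and mRNA decay lists passed the test and the other 5 did not (adjusted p from 0.586 to 0.676). In that list 863 genes in place of 3283 had a peak, and the odds ratios were 2.68 for germline identity, 2.17 for germ plasm and axis, 1.752 for meiosis and egg activation, 12.2 for ribosomal proteins and 5.55 for mRNA decay. With a TSS window of 100 bp the testis-specific list no longer passed (Fisher's exact test, adjusted p = 0.0634).

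**Figure D2:**
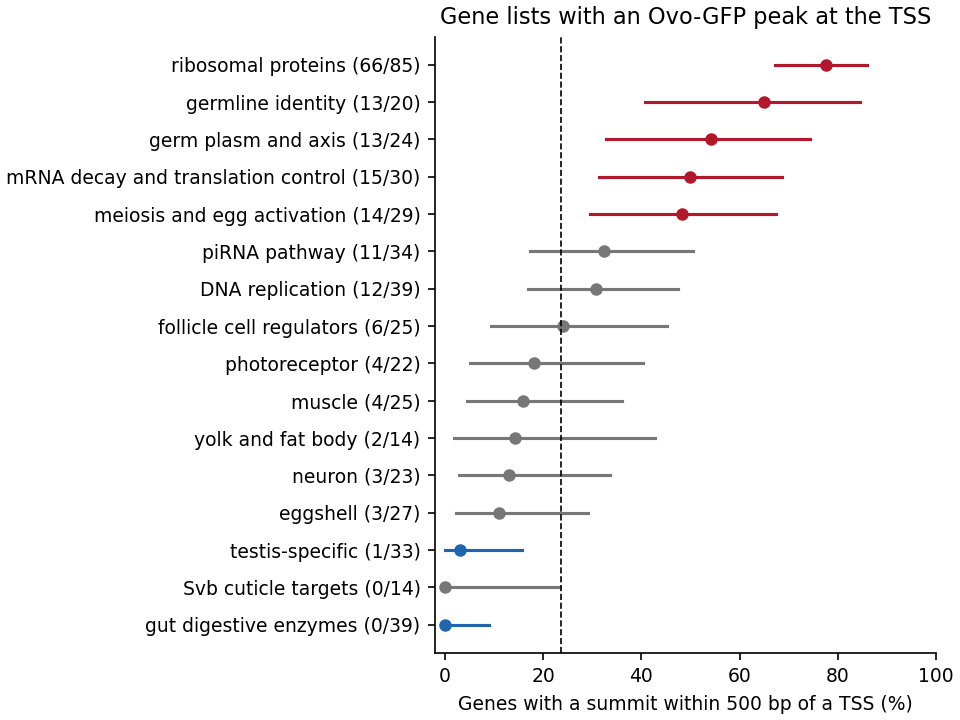
Percent of the genes of each list with a thresholded summit within 500 bp of a TSS (points) and 95% Clopper-Pearson intervals (lines), with the number of genes beside each name. The dashed line is the 23.5% of all 13945 protein-coding genes; red and blue lists lay above and below it with adjusted p under 0.05, from 77.6% of ribosomal protein genes to 0% of gut digestive genes.

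Most peaks were at promoters. A summit lay within 500 bp of a TSS in 2851 of 4477 thresholded peaks (63.7%, interval 62.3 to 65.1), against a mean of 11.5% after rotation and at most 13.7% in 1000 rotations (one-sided permutation test, p = 0.000999, the smallest they can give). Promoter summits had a median position of -57 bp from the nearest TSS with quartiles of -131 and 14 bp, and 70.9% lay upstream. Introns held 25.8% of the summits (39.3% after rotation) and sequence outside protein-coding genes 7.53% (29.9%). Coding exons held 0.424% (13.2%) and 3' UTRs 1.16% (5.23%), while 5' UTRs beyond the promoter window held 1.38% (0.796%). With a window of 100 bp the promoter share was 34.3%, still above rotation (2.73%).

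Genes with a peak also differed in their core promoters. The TSS used was the one nearest to a summit for genes with a peak and the 5'-most for the others. The 2 groups were thus measured at differently chosen positions, and genes that share a peak counted separately. A TATA box was present in 3.35% of 3283 genes with a peak and in 11.2% of 10662 without (odds ratio 0.275, interval 0.224 to 0.337, Fisher's exact test, adjusted p = 4.06e-49). The Initiator was also less frequent with a peak (10.8% against 12.9%, odds ratio 0.818, Fisher's exact test, adjusted p = 0.00133). The DRE, a site of housekeeping promoters, was more frequent (10.7% against 6.42%, odds ratio 1.74, Fisher's exact test, adjusted p = 1.11e-14), as was Motif 1 (9.32% against 5.50%, odds ratio 1.77, adjusted p = 7.82e-14). With the 1000 peaks of highest score only the TATA box difference passed the test (odds ratio 0.208); the odds ratios of the DRE and Motif 1 were then 1.15 and 0.928, with adjusted p of 0.412 and 0.67.

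The Ovo core site was more frequent at summits than beside them. TAACNGT was present within 50 bp of 651 summits (14.5%, interval 13.5 to 15.6) and in 2.88% of windows 500 bp away, a ratio of 5.05 (exact McNemar tests, p = 1.04e-81 and 2.07e-100 for the left and right side). The permuted pattern TNACAGT was at 6.90% against 3.82%, a ratio of 1.81. Among the sites of other factors, the DRE (2.55% against 0.436%, ratio 5.85) and Motif 1 (1.72% against 0.313%, ratio 5.50) were also more frequent at summits, with ratios above that of the Ovo site, as was the GAGA factor site (4.65% against 2.26%, ratio 2.06), whereas the E-box CACCTG (3.91% against 4.12%) and the Zelda site (0.424% against 0.614%) were not. The core site was present at 13.7% of promoter summits and 15.9% of the others (odds ratio 1.19, interval 0.998 to 1.41, Fisher's exact test, p = 0.0474).

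Stronger peaks had the site more often. It was at 23.9% of summits in the 895 peaks with the highest score and at 10.6% in the 896 with the lowest (odds ratio 2.65, interval 2.02 to 3.48, Fisher's exact test, p = 5.86e-14). Among peaks away from TSSs it was at 31.1% of the 325 with the highest score and 9.20% of the 326 with the lowest, and among promoter peaks at 19.6% of 570 and 11.6% of 571. In the 15000 peaks with the lowest score in the pooled list, a reference chosen after seeing the data, the site was at 2.70% of summits and in 2.33% of the flanks, and 17.2% of summits were near a TSS.

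**Figure D3:**
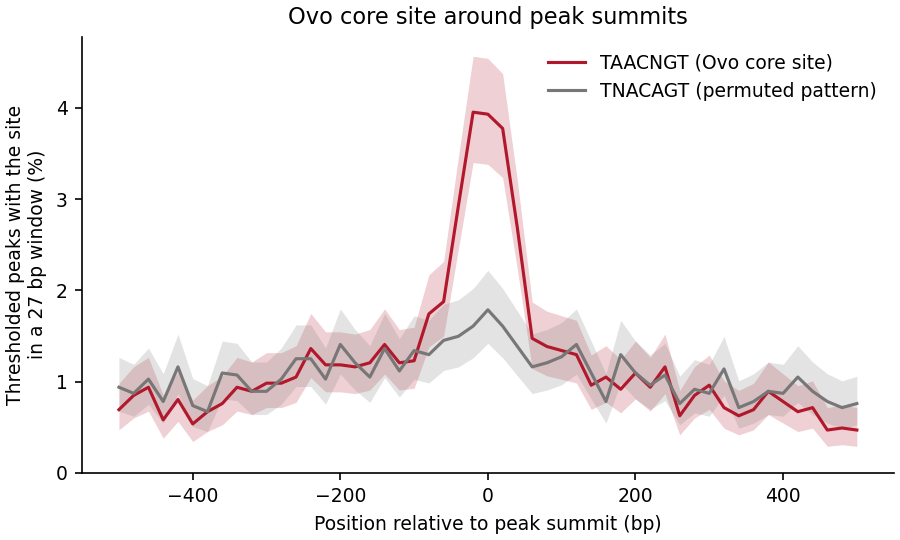
Percent of the 4477 thresholded peaks with TAACNGT (red) or the permuted pattern TNACAGT (grey) in a 27 bp window, by the window's position relative to the summit (bp), with 95% Clopper-Pearson intervals shaded. The Ovo core site peaks at 3.95% next to the summit.

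**Figure D4:**
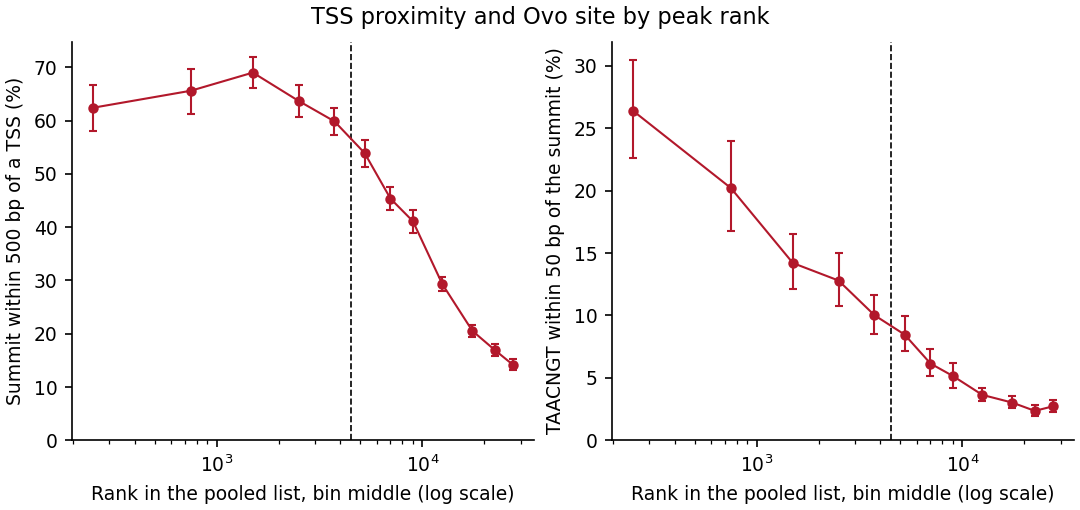
Percent of summits within 500 bp of a TSS (left) and with TAACNGT within 50 bp (right), by rank in the pooled list (bin middle, log axis), with 95% Clopper-Pearson intervals; the dashed line marks rank 4477, the end of the thresholded list. The site share is 26.4% in the first 500 peaks and 2.72% in the last bin, and the TSS share is highest, at 69.0%, in ranks 1001 to 2000.

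A search of all 6-mers gave the same site without a prior pattern. TAACGG (reverse complement CCGTTA) came first, in 16.6% of summit windows and 1.91% of flanking windows (ratio 8.70, Fisher's exact test, adjusted p = 8.05e-208), and AACGGT, which overlaps it by 5 bases, came second (14.6% against 2.71%, ratio 5.37, adjusted p = 1.37e-135). Of 2080 6-mers, 304 were more frequent at summits and 418 less frequent. TAACGG came first among promoter peaks (ratio 8.45) and among the others (ratio 9.11). At promoters CGATAG, which overlaps the DRE, followed these 2 (9.79% against 2.58%). CCAGGA was the first of the less frequent 6-mers, at 0.648% against 4.29%. Summits and flanks also differed in their content of G and C bases. It was 40.9% against 44.1% for promoter peaks and 43.4% against 38.9% for the others. The windows were not matched for base composition, so how many of the 6-mer calls reflect it is not known.

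Peaks were more frequent on X. X held 1031 of the 4477 peaks (23.0%, interval 21.8 to 24.3), or 43.8 per Mb (exact Poisson interval 41.2 to 46.6). The densities were 32.1 per Mb on 2L, 33.4 on 2R, 28.6 on 3L and 32.2 on 3R, and chromosome 4 held 11 peaks, 8.16 per Mb. The ratio of X to the large autosomal arms was 1.39 (interval 1.29 to 1.49, exact binomial test, p = 2.57e-19), 1.46 per protein-coding TSS cluster and 1.64 in the 1000 peaks of highest score. On dm3 X held 23.8% of the 2986 thresholded peaks.

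The replicates shared most of their best peaks. Of the 4477 best peaks of replicate 1, 67.3% (interval 65.9 to 68.7) had a summit within 100 bp among those of replicate 4, against 0.686% after rotation (permutation test by 1000 rotations, p = 0.000999, the smallest they can give). The share was 72.2% for the first 1000 peaks of each list and 40.3% for the whole relaxed lists. The thresholded peaks were called on the reads of both replicates together, so their presence in each replicate is partly built in. Of them, 92.0% had a counterpart in both relaxed lists, 3038 were among the best 4477 of both replicates and 124 in neither. Across the 4119 peaks found in both, the ranks had a Spearman correlation of 0.648 (interval 0.624 to 0.669). It is a correlation across peaks, which are not independent replicates.

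On dm3 the thresholded list was shorter, with 2986 peaks in place of 4477, and the relaxed lists held 20048 (replicate 1), 16841 (replicate 4) and 16129 (pooled) peaks where each dm6 list held 30000. Each dm6 relaxed list thus ended at the same round number and the dm3 lists did not, so lists of different builds were not compared peak by peak.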

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

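Peaks on sequences outside the 6 chromosome arms were left out of the comparisons above and occur in the dm3 relaxed lists. There were 51 in replicate 1, 34 in replicate 4 and 31 in the pooled list. None of the 2986 thresholded dm3 peaks lay there, and all dm6 peaks lay on the arms.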

How the results depend on the processing

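The alternatives with the 15000 lowest-scoring pooled peaks as the reference, with a ratio per Ovo site and with a background without ribosomal protein genes, as well as the gene families and the split of the Ovo site, were chosen after seeing the data. The 4477 best peaks of the pooled list are the thresholded list itself, so setting one against the other tested nothing. For the dm3 lists no peaks per Mb were computed, since dm3 arm lengths were not used here. Excluding the identical list, 173 values of the main results stayed on their side of the threshold. Of these, 11 gene list values, past the threshold in neither setting, changed side of 1, including 4 with the 1000 best peaks (piRNA 0.947, DNA replication 0.819, yolk and fat body 1.17, follicle cell 0) and 4 against rotated peaks. The ratio of site frequency at summits to flanks ranged from 2.73 (TAACNG) to 7.64 (1000 best peaks), the ratio of X to autosomes from 1.38 to 1.64, the share near a TSS from 34.3% to 73.5% and the share of peaks matched between replicates from 40.3% to 78.3%; leaving out replicate 1 or replicate 4 ended no call among the main results, but without replicate 1 the odds ratio of the germline identity list was 9.86, and without replicate 4 it was 5.12.

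With the 1000 best peaks, 2 gene lists passed the test in place of 7 and 87 6-mers were more frequent at summits in place of 304. Odds ratios were then 2.68 for germline identity, 2.17 for germ plasm, 1.752 for meiosis, 0 for gut and 0 for testis genes, none past the threshold; this list is smaller by construction. The Initiator (odds ratio 0.886) and the DRE (1.15) also lost their calls there, and Motif 1 turned to 0.928; the cause was not tested. With a 100 bp window the testis list had an odds ratio of 0 and Fisher's exact test, adjusted p = 0.0634. Counting summits anywhere in the gene body, follicle cell regulators passed, with an odds ratio of 3.05; the cause was not tested. Against rotated peaks, the piRNA (8.91-fold), follicle cell (4.51-fold) and DNA replication (8.09-fold) lists passed and the photoreceptor list turned from an odds ratio of 0.721 to 4.28-fold. Without passing, the eggshell (3.34-fold), yolk and fat body (4.49-fold), muscle (2.97-fold) and neuron (2.16-fold) lists also turned from below to above 1, while the gut (0-fold) and testis (0.894-fold) lists lost their calls. Rotation compares with random positions, at which 3.74% of all genes had a summit in place of 23.5%, so by construction it asks another question. Among named genes, families and sites, 240 values stayed on their side of the threshold or window, 40 lost it, 33 of them with the 1000 best peaks, and 3 gained one. Unknown read depth limits all of these values.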

Other observations

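The tests on gene families, on the variable base of the Ovo site, on X at low ranks, on snRNA, snoRNA and other non-coding RNA genes, and on tRNA genes with summits away from coding TSSs were chosen after the data were seen. The other tests of explanations were written before their values were seen, although the patterns themselves had been seen, and the rules for reading the ribosomal protein, tRNA and unmatched peak tests were revised once the values were known, which changed no reading.

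The variable base of the core site was mostly G at the summits. TAACGGT was within 50 bp of 398 summits (8.89%, interval 8.07 to 9.76) and in 0.558% of flanking windows, a ratio of 15.9 (exact McNemar tests, p = 1.51e-81 and 1.42e-102). The ratio was 3.52 for TAACTGT, 3.33 for TAACCGT and 2.34 for TAACAGT, although TAACTGT (14295) and TAACAGT (11674) occur more often on the arms than TAACGGT (7719). With the 1000 best peaks the ratio of TAACGGT was 21.4, and TAACAGT no longer passed (ratio 2.55, exact McNemar test, p = 0.115).

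Gene families defined by symbol differed widely. Mitochondrial ribosomal protein genes had a peak at the TSS in 32 of 73 cases (43.8%, odds ratio 2.55, Fisher's exact test, adjusted p = 0.000275) and translation initiation factor genes in 17 of 44 (38.6%, odds ratio 2.05, adjusted p = 0.0408). The first did not pass with a 100 bp window (odds ratio 1.49, Fisher's exact test, adjusted p = 0.313) and the second did not pass with replicate 4 alone (odds ratio 1.87, adjusted p = 0.0659). Proteasome subunits (14 of 48, Fisher's exact test, adjusted p = 0.393) and complex I subunits (12 of 40, adjusted p = 0.393) did not pass, and the proteasome odds ratio went from 1.34 to 0.654 without replicate 1. None of 59 odorant receptor, 60 gustatory receptor and 92 cuticle protein genes had a peak (Fisher's exact test, adjusted p = 5.62e-07, 5.26e-07 and 2.14e-10), and 8 of 85 cytochrome P450 genes did (odds ratio 0.336, adjusted p = 0.00192). The P450 call was lost with a 100 bp window (odds ratio 0.571), and with the 1000 best peaks all 6 family calls were lost (adjusted p from 0.0558 to 0.234). The odds ratios were then 1.87 for mitochondrial ribosomal proteins, 2.88 for initiation factors, 0.364 for P450 genes and 0 for the other 3 families. Within 100 kb centred on ovo there were 11 thresholded peaks, against a median of 3 and at most 20 in 235 windows of X. Nearly all of these windows held no more than 14, so the ovo window lay above the median but within their usual range. In the pooled list the ovo window held 50 peaks, against a median of 24 and an upper limit of the usual range of 52.15.

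For the frequent peaks at ribosomal protein promoters, an excess of TAACNGT sites in the DNA was argued against. Ribosomal protein genes had TAACNGT within 250 bp of a TSS no more often than other genes (odds ratio 0.774, interval 0.411 to 1.37). Its form TAACGGT was not counted separately there, and no other site was tested at these promoters. Signal at active promoters without a site may contribute, since 3.03% of their peaks had the site at the summit, near the 2.27% in the flanks and below the 14% of other promoter peaks. Of tRNA genes, 7.93% had a summit within 500 bp against 3.11% after rotation, and 6.21% against 1.06% from summits away from coding TSSs, whereas snRNA genes had 18.75% (permutation test by rotation, p = 0.004) and snoRNA genes 5.58%, not above rotation (p = 0.114). The 3261 other non-coding RNA genes were also above rotation (6.29% against 3.05%), so such an excess was not particular to these classes, and signal at highly transcribed genes stays open; whether the peaks at tRNA genes lack the site was not tested. A control precipitation from flies with GFP alone was not analysed here, so binding of Ovo through other proteins and signal independent of Ovo stay open.

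The excess of peaks on X was not matched by its number of TAACNGT sites or by peaks of low score. More TAACNGT sites on X were argued against by their density. The ratio of X to autosomes was 1.01 (interval 0.979 to 1.03), below the 1.29 that is the lower limit for peaks. TAACGGT, the form with the highest ratio at summits, was not counted by arm, so more of that form on X stays open. In the 15000 pooled peaks of lowest score the ratio of peaks per Mb was 1.03 (interval 0.992 to 1.08). In the last 10000 it was 1.06 (exact binomial test, p = 0.0159). The list was cut at 30000 peaks, and a gain of signal would also move X peaks up its ranks. The low ranks therefore did not settle whether signal was higher on the whole X relative to the control. The ratio was 1.64 in the first 1000 ranks, 1.37 in ranks 1001 to 2000 and 1.198 in ranks 4478 to 10000. Beyond the number of sites, no biological explanation was tested, and the source of the excess stays open.

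Of the best 4477 peaks of each replicate, 1463 had no counterpart in the other's best 4477, which gives 2926 unmatched peaks in the 2 lists together. Of these, 60.2% (interval 58.4 to 62.0) had a summit within 100 bp in the other's relaxed list, against 4.55% after rotation. The median ranks of all unmatched peaks in their own lists were 3309 and 3277. The ranks of the counterparts were not examined, so rank near the edge of the list may account for many unmatched peaks but was not shown to. Signal without an Ovo site was argued against as the whole cause: 9.47% of them had the site at the summit, against 2.99% in the flanks (exact McNemar tests, p = 3.54e-24 and 1.38e-26), although less than the 16.6% of matched peaks (Fisher's exact test, p = 2.44e-16). No biological explanation was tested, as both replicates belong to 1 group, and the cause of the unmatched peaks stays open.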
